A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

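Total RNA from 6 cultures of Saccharomyces cerevisiae VTT C-10883 was labelled with biotin by a 3' in vitro transcription kit and read on Affymetrix arrays that also carry probe sets for fission yeast. The groups, 3 cultures without inhibitors and 3 with HMF and furfural, and their description as biological replicates come from the labels. The dose, the time after the switch and the dilution rate are not given in the sources used here.

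The values are log2 signals as deposited by the authors, and per the submitters' processing notes GCRMA and limma were used, with versions not given in the sources used here. GCRMA corrects background by probe sequence and normalizes between arrays, so low signals gather at a floor (lowest value 2.21), and changes of genes near that floor are understated. No further normalization was applied. The table held 10762 probe sets. The platform annotation paired 7244 of them with 1 gene, 1 with several genes, and left 3517 unlisted. Of those with 1 gene, 5498 belonged to S. cerevisiae and 1746 to fission yeast. Fission yeast probe sets gave the background: a gene was above background on an array when it passed their 95th percentile there. Names were matched to the RefSeq table of assembly R64, which renamed 12 genes. That table was used for names and gene order alone, and no coordinates are given because the array annotation names no genome build. For 47 genes with over 1 probe set, the set with the highest mean signal was used, and in 0 of these genes did called sets disagree in sign. Probe sets marked as able to cross-hybridize read 117 genes.

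Groups were compared in limma 3.58.1 under R 4.3.3 by a linear model with empirical Bayes moderation, two-sided, with Benjamini-Hochberg adjustment over 5449 genes and a threshold of 0.05. The fit had group as its single factor. In total 49 gene lists were tested by limma's camera with a preset inter-gene correlation of 0.01, adjusted over the 49 lists, and again with an estimated correlation, under which none of them was called. As an alternative, limma's fry tested whether the genes of a list moved on balance in a single direction. The group comparison, the list test, the lists, the alternatives and the rule for named genes were fixed before the data were examined. That rule took the 12 genes with the largest rise and the 12 with the largest fall among called genes whose groups did not overlap, up to 4 called members of each list by size of change, and a fixed set of aldehyde, redox and control genes. The closing section names the tests of explanations that were chosen later. Genes named outside the rule there were chosen after their values were seen.

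The tests were tested on 10 simulated data sets of 5449 genes with 200 changed. They recovered 53.0% of changes of 0.25 on the log2 scale, 88.2% of changes of 0.5 and 99.2% of changes of 1, and 4.47% of calls were false. With no change simulated there were 0 calls on average. Noise was drawn independently for each gene, and changes were placed only in genes well above the floor. In the data 2300 genes were called, so these rates need not hold there. Alternatives covered normalization, an intensity filter, variance moderation, array weights, the replicate number as a block, the treatment of probe sets, the threshold, the set test and leaving out each replicate. Control probe sets for the 3' and 5' ends of transcripts were not used here, so RNA quality was not checked. Unlisted probe sets were left out of the gene and list tests and are given apart in the closing section, and 1 further test is not reported here. Figures were drawn with matplotlib 3.10.9.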

Results

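Transcript levels were measured in Saccharomyces cerevisiae VTT C-10883 grown without oxygen in chemostats, continuous cultures fed with fresh medium. RNA came from 3 biological replicates without inhibitors and from 3 replicates whose feed had been switched to medium with 5-hydroxymethylfurfural (HMF) and furfural, 2 aldehydes formed when plant sugars break down. Each of the 6 arrays gave a log2 signal for 5449 genes. Of these, 5346 lay above background on all 6 arrays, a level that lies just above the floor. The number of arrays limits the precision. The within-group SD had a median of 0.06 on the log2 scale. Pairs of arrays correlated across genes at r = 0.998 to 0.999 within groups and at r = 0.989 to 0.994 between groups, and the first principal component, with 82.7% of the variance, separated the groups.

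The comparison asked how the yeast's transcripts differed between cultures with both aldehydes and cultures with neither. With inhibitors, 26 of 36 general stress genes and 24 of 36 respiratory chain and ATP synthase genes fell and none of either list rose (camera adjusted p = 8.91e-08 and 1e-06; adjusted p = 0.641 for both with an estimated correlation). The drug efflux pump gene PDR5 rose from 7.73 to 9.38, a log2 fold change of 1.65 (SE 0.05, adjusted p = 0.000317), and the flocculin gene FLO11, needed for adhesion and filamentous growth, rose by 2.20 (SE 0.07, adjusted p = 0.000317). The small stress protein gene HSP12 fell by 1.97 on the log2 scale (SE 0.32, adjusted p = 0.00679), and the general amino acid permease gene GAP1 fell by 1.61 (SE 0.13, adjusted p = 0.00102). Each of these values compares 3 arrays with 3 in limma's moderated test with Benjamini-Hochberg adjustment.

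In all, 1086 genes were higher and 1214 lower with inhibitors at an adjusted p under 0.05 in limma, together 42.2% of those tested. Most changes were small: 2083 of the 2300 were under 1.5-fold, and the median size was 0.26 on the log2 scale. At 2-fold or more, 21 genes were higher and 36 lower. The values of the groups did not overlap for 3018 genes, or 55.4%, where chance gives 10%.

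The 12 largest rises were led by YMR317W, a gene of unknown function, which went from 3.73 to 6.49 (log2 fold change 2.76, SE 0.14). YGR035C rose by 2.05, the isomaltase gene IMA5 by 1.99, the cell wall mannoprotein gene TIR2 by 1.68, the seripauperin gene PAU5 by 1.64, SFG1, a regulator of filamentous growth, by 1.43, and the hexose transporter family gene HXT8 by 1.29. The cell wall mannoprotein gene DAN4 rose by 1.27, PRM9 by 1.26 and ANS1 by 1.22. The largest falls were those of HPF1, a cell wall mannoprotein gene, which fell by 2.60 (SE 0.15), and CWP1, another, which fell by 2.17. PNS1 fell by 2.04, AGX1, which makes glycine from glyoxylate, by 1.83, FMP16 by 1.74 and the phosphate transporter gene PHO84 by 1.62. The permease genes BAP3, MUP1 and GNP1 fell by 1.61, 1.59 and 1.58, and the membrane heat shock protein gene HSP30 fell by 1.58. Adjusted p in limma lay between 0.00025 and 0.00838 for these 24 genes.

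**Figure D1:**
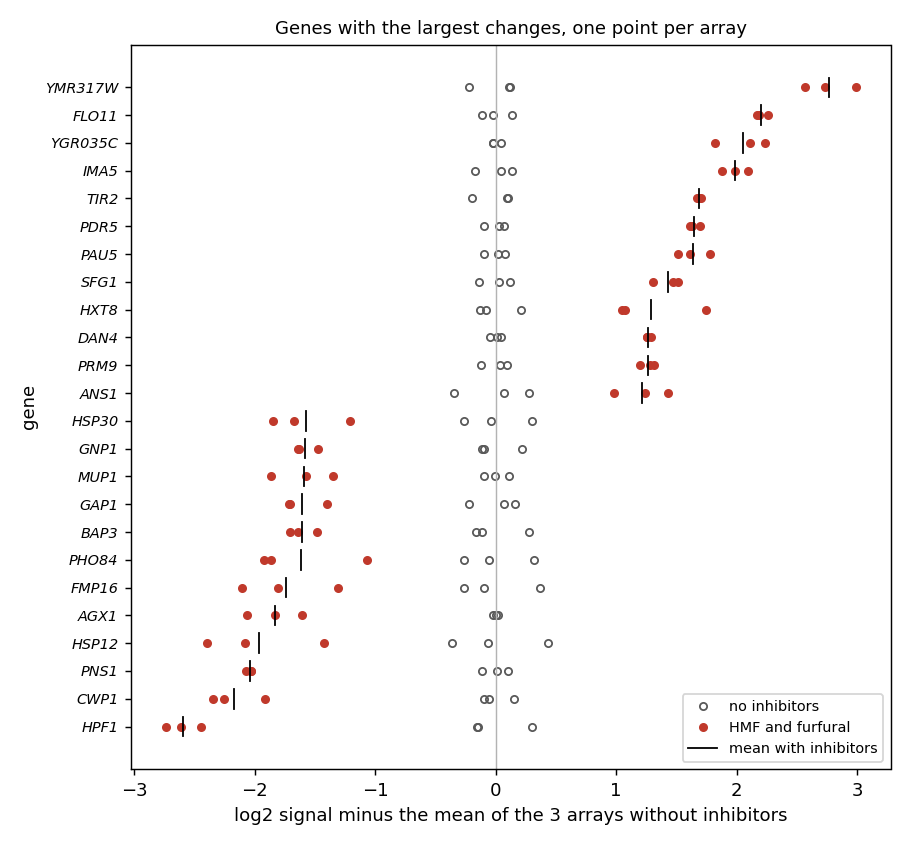
Log2 signal of the 12 genes that rose most and the 12 that fell most, as the difference from the mean of the 3 arrays without inhibitors, with 1 point per array and a bar at the mean with inhibitors. The 3 arrays with inhibitors lay apart from the 3 without in each of the 24 genes.

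Genes of furan aldehyde reductases and of aldehyde dehydrogenases, tested as 1 list, did not rise as a group. Of 19 measured reductases and aldehyde dehydrogenases, 2 rose, 7 fell and 10 were not called (2 and 7 adjusted over the list alone; mean log2 fold change -0.11, camera adjusted p = 0.147). ADH6, an NADPH-dependent HMF reductase gene, fell by 0.23 (adjusted p = 0.00752), SFA1 by 0.32 and the aldehyde dehydrogenase gene ALD5 by 0.45. ADH4 rose by 0.25 (adjusted p = 0.0265 in limma), a call lost under 5 alternatives. GRE2 had a log2 fold change of 0.13 (adjusted p = 0.261), ARI1 of -0.09 (adjusted p = 0.245) and ALD6 had an adjusted p of 0.988. ADH7 was not above background. Of 7 aryl-alcohol dehydrogenase and old yellow enzyme genes, 1 rose and 5 fell (1 and 5 adjusted over the list alone; camera adjusted p = 0.083), among them OYE3, which fell by 0.83, and AAD6, which fell by 0.66.

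Drug resistance genes moved both ways. Of 23 measured, 9 rose, 5 fell and 9 were not called (10 and 5 adjusted over the list alone), with a mean of 0.19 and a camera adjusted p of 0.221. PDR5 and YGR035C were joined by ICT1 and PDR16, a lipid transfer protein gene, each of which rose by 1.01. The regulator gene PDR1 had a log2 fold change of -0.06 (adjusted p = 0.16).

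General stress genes fell most as a group. Of 36 genes driven by the stress regulators Msn2 and Msn4, 26 fell, none rose and 10 were not called (30 fell adjusted over the list alone), with a mean of -0.66 and a camera adjusted p of 8.91e-08 (adjusted p = 0.641 with an estimated correlation). HSP26, a small chaperone gene, fell by 1.44, and MSN4 itself fell by 0.55. In trehalose and glycogen metabolism 16 of 21 genes fell and 1 rose (16 and 2 adjusted over the list alone; camera adjusted p = 0.000524, and adjusted p = 0.641 with an estimated correlation). PGM2, GLC3 and GPH1 fell by 1.15, 0.90 and 0.85. In the pentose phosphate pathway 13 of 19 fell and none rose (14 fell adjusted over the list alone; camera adjusted p = 0.00145, and adjusted p = 0.546 with an estimated correlation), including SOL4, which fell by 1.17, GND2, by 1.12, and ZWF1, which makes NADPH, by 0.31. GND1 had a log2 fold change of -0.18, at a mean signal without inhibitors of 12.6 against 7.28 for GND2. The median of the pathway's list was also -0.18. These lists share genes: TPS1, PGM2 and NTH1 are also stress list members, as are SOL4 and TKL2 of the pentose phosphate list. Heat shock and chaperone genes gave 6 rises and 9 falls among 31 (6 and 12 adjusted over the list alone; camera adjusted p = 0.233), and HSP78 fell by 0.86. Oxidative stress and Yap1 target genes gave 6 rises and 15 falls among 37 (6 and 15 adjusted over the list alone; camera adjusted p = 0.192). FRM2 and HBN1 rose by 0.78 and 0.69, and YAP1 had a log2 fold change of -0.02 (adjusted p = 0.696).

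Respiratory genes fell together by small amounts. Of 36 genes of the respiratory chain and ATP synthase, 24 fell and none rose (25 and 1 adjusted over the list alone), with a mean of -0.24 and a camera adjusted p of 1e-06 (adjusted p = 0.641 with an estimated correlation). INH1 and NDI1, the internal NADH dehydrogenase gene, fell by 0.65 and 0.59. Of 22 genes on the tricarboxylic acid cycle list, which also holds genes of linked reactions such as PYC1 and PYC2, 12 fell and 2 rose (13 and 2 adjusted over the list alone; camera adjusted p = 0.00307, and adjusted p = 0.662 with an estimated correlation). The list members MDH2 and SDH1 were down by 0.75 and 0.62 (log2 fold changes of -0.75 and -0.62). Of 71 mitochondrial ribosomal protein genes 24 fell and 3 rose (24 and 3 adjusted over the list alone; camera adjusted p = 0.00771, and adjusted p = 0.546 with an estimated correlation), MRPS18 by 0.37 (log2 fold change -0.37). In peroxisomes and fatty acid oxidation 9 of 21 fell and 1 rose (9 and 1 adjusted over the list alone; camera adjusted p = 0.0258, 0.0511 without no-inhibitor replicate 2, and adjusted p = 0.641 with an estimated correlation), and the thiolase gene POT1 fell by 1.42. Of 34 autophagy genes 11 fell and 3 rose (11 and 3 adjusted over the list alone; camera adjusted p = 0.0312, and adjusted p = 0.641 with an estimated correlation). That call was lost without no-inhibitor replicate 2 (adjusted p = 0.0526) or inhibitor replicate 2 (adjusted p = 0.0642). Gluconeogenesis and glyoxylate cycle genes gave 1 rise and 6 falls among 18 (1 and 5 adjusted over the list alone; camera adjusted p = 0.12).

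Of 27 genes repressed by good nitrogen sources, 15 fell and 2 rose (15 and 2 adjusted over the list alone; camera adjusted p = 0.00145, and adjusted p = 0.643 with an estimated correlation). AGP1, a broad-range permease gene, fell by 0.87 and the urea transporter gene DUR3 by 0.63. Of 8 arginine biosynthesis genes 4 fell and 1 rose (5 and 1 adjusted over the list alone; camera adjusted p = 0.0333, 0.0622 without inhibitor replicate 1, and adjusted p = 0.641 with an estimated correlation), ARG4 with a log2 fold change of -0.72. Of 25 mating-type and pheromone genes 18 fell and 2 rose (19 and 2 adjusted over the list alone; camera adjusted p = 0.00192, and adjusted p = 0.662 with an estimated correlation), and the pheromone receptor gene STE2 fell by 1.03. Lysine biosynthesis gave 5 falls and 1 rise among 9 (6 and 1 adjusted over the list alone; camera adjusted p = 0.0833), and the remaining amino acid biosynthesis genes gave 16 falls and 7 rises among 37 (17 and 8 adjusted over the list alone; camera adjusted p = 0.0985). Among 35 sulfur assimilation genes 11 rose and 8 fell (12 and 8 adjusted over the list alone; camera adjusted p = 0.615), and the sulfate permease gene SUL1 rose by 0.72.

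Of 22 hypoxic and anaerobic genes 13 rose and 5 fell (13 and 5 adjusted over the list alone), with a mean of 0.32 and a camera adjusted p of 0.0299 (adjusted p = 0.662 with an estimated correlation). The call was lost under quantile normalization (adjusted p = 0.0528) and without cross-hybridizing probe sets (adjusted p = 0.106). Without the 2 members read by such sets, PAU24 and PAU7, the mean was 0.25 over 20 genes (standard error over genes 0.136) against 0.32 over 22 (standard error 0.135). TIR2, DAN4 and PAU24 rose by 1.68, 1.27 and 1.21. Of 19 flocculin and PAU genes 6 rose and 7 fell (7 and 7 adjusted over the list alone; camera adjusted p = 0.592), 11 of them read by probe sets that can cross-hybridize. Cell wall genes gave 4 rises and 11 falls among 26 (4 and 12 adjusted over the list alone; camera adjusted p = 0.083), and SED1, a structural wall protein gene, fell by 0.98.

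Genes for making ribosomes and for protein turnover were slightly higher. Of 131 ribosome biogenesis genes 42 rose and 9 fell (42 and 9 adjusted over the list alone; camera adjusted p = 0.00307, adjusted p = 0.057 by fry, and adjusted p = 0.666 with an estimated correlation), and NOP15 rose by 0.53. Of 25 genes of RNA polymerases I and III 8 rose and none fell (7 rose adjusted over the list alone; camera adjusted p = 0.0299, and adjusted p = 0.662 with an estimated correlation), with RPC34 at 0.61. That call was lost without inhibitor replicate 2 (adjusted p = 0.0615) or 3 (adjusted p = 0.0694). Of 47 proteasome and ubiquitin genes 20 rose and 5 fell (21 and 6 adjusted over the list alone; camera adjusted p = 0.0255, and adjusted p = 0.641 with an estimated correlation). RPN5 rose by 0.60, and RPN4, the activator of proteasome genes, by 0.22. Of 10 histone genes 6 rose and 1 fell (7 and 1 adjusted over the list alone; camera adjusted p = 0.00961, and adjusted p = 0.641 with an estimated correlation), and HTZ1 rose by 0.51. In purine and one-carbon metabolism 10 of 23 rose and 3 fell (10 and 3 adjusted over the list alone; camera adjusted p = 0.0169, and adjusted p = 0.641 with an estimated correlation), and ADE1 rose by 0.54. Cytosolic ribosomal protein genes were mostly not called: 16 of 128 rose and 3 fell (12 and 2 adjusted over the list alone; camera adjusted p = 0.0985). The list's name pattern also took in RPP1, an RNase P subunit gene that is no ribosomal protein gene and is among the rises, a call lost without no-inhibitor replicate 1 or 2 or inhibitor replicate 2 (adjusted p = 0.055, 0.058 and 0.0501). Ergosterol biosynthesis gave 10 rises and 2 falls among 26 (10 and 3 adjusted over the list alone; camera adjusted p = 0.083).

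Glycolysis genes were mostly not called. Of 20 glycolysis and ethanol formation genes 2 rose and none fell (2 adjusted over the list alone; camera adjusted p = 0.592), the hexokinase gene HXK2 by 0.26. Of 7 xylose and polyol genes 5 fell (5 adjusted over the list alone; camera adjusted p = 0.12), GRE3 by 0.24, and the xylulokinase gene XKS1 had a log2 fold change of 0.06 (adjusted p = 0.129). Glycerol metabolism gave 1 rise and 5 falls among 12 (1 and 5 adjusted over the list alone; camera adjusted p = 0.496), and hexose transport and sensing 4 and 6 among 21 (4 and 6 adjusted over the list alone; camera adjusted p = 0.592). The actin gene ACT1 had a log2 fold change of 0.01 (adjusted p = 0.841).

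**Figure D2:**
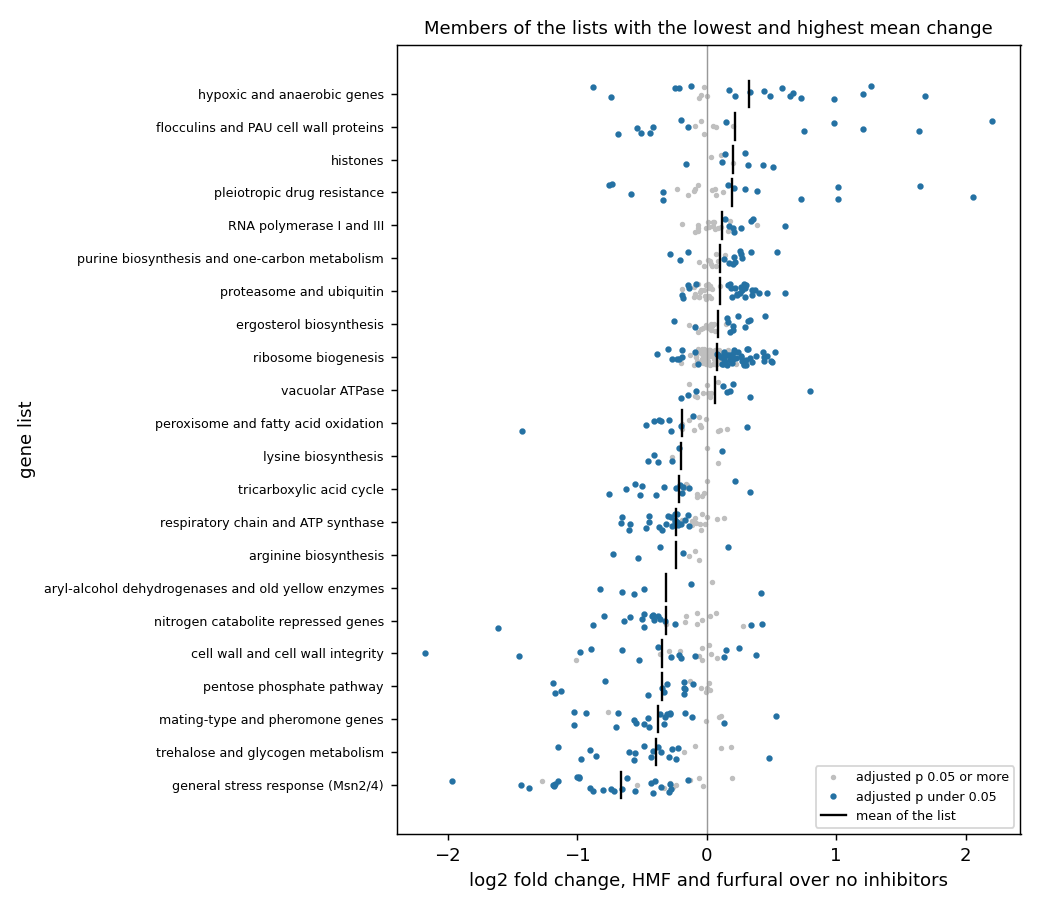
Log2 fold change of every measured member of the 12 gene lists with the lowest mean and the 10 with the highest, with 1 point per gene, coloured by whether its adjusted p in limma was under 0.05, and a bar at the list's mean. The stress list lay lowest, with a mean of -0.66, and the hypoxic list highest, with a mean of 0.32.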

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

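The tests of 1 deviating array and of faster growth below were chosen after the stress list's fall had been seen.

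Of 319 probe sets with no gene in the annotation used, all above background on all 6 arrays, 41 were higher with inhibitors and 52 lower, 1 of them by 2-fold or more. Some of the 319 lay near the floor, at 2.22 with an SD of 0 in both groups, so passing background does not show a signal. The 319 drew attention because they lie outside the report's comparison. Among them, 4 of 8 reporter and vector control probe sets were higher, by 0.30 to 0.51 on the log2 scale, and their identity was not tested.

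The fall of the general stress genes is the pattern weighed first. A fall made by a single deviating array alone would leave no space between the groups. The lowest array without inhibitors exceeded the highest with them by 0.3515 in the list's mean, more than the larger within-group SD of 0.1788. This cannot show whether 1 array changed the size of the fall. Without inhibitors, replicate 3 had a mean of 7.90 against 7.62 and 7.68, which widened the fall. With them, replicate 1 had 7.27 against 7.02 and 6.93, which narrowed it. Faster growth in the inhibitor cultures would raise both ribosomal lists, and 1 of the 2, ribosome biogenesis, was called higher. That call was lost by fry (adjusted p = 0.057) and had an adjusted p = 0.666 with an estimated correlation. The test thus decides neither for nor against faster growth, which cannot be told apart from an effect of the aldehydes. The cultures were chemostats, and their dilution rate and the time after the switch are not given, so growth rates could not be compared.

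The 6 arrays can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split called 1086 genes higher and 1214 lower, and 21 and 36 at 2-fold or more, with 0 as the highest count of any other split, so 1 of the 10 gave as many. It called 6 lists higher and 11 lower, with 14 as the highest of the others, and 5 and 2 of the 10 splits gave as many. Each of the other splits mixes the groups, which puts the difference between them into the spread. This lowers gene calls in those splits, but it did not hold list calls down. The mixed split with the most list calls had 14 in 1 direction and 5 in the other. The list counts therefore do not set the real split apart.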

How the results depend on the processing

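No called named gene and no called list changed sign under any alternative. Among those not called, ALD6, YAP1, ACT1 and ADH7 and the means of the G1/S, glycolysis and unfolded protein response lists lay on both sides of 0. More genes fell than rose, except under quantile normalization (1251 higher, 1126 lower), without no-inhibitor replicate 1 (937 and 868) and at the stricter threshold. At an adjusted p under 0.01, limma called 608 genes higher and 582 lower and camera called 2 lists higher, as a stricter threshold must lower counts. With an estimated correlation camera called 0 lists higher and 0 lower. The pentose phosphate, mitochondrial ribosomal and arginine lists had estimated correlations of -0.0071, 0.0045 and 0.0089, below the preset 0.01. A higher correlation therefore does not explain the loss of their calls. The general stress and respiratory lists had estimates of 0.467 and 0.288, above the preset. For these 2 lists, camera's preset results rest on a lower correlation than the one estimated. The test called fry, which asks whether a list's genes move 1 way, called 8 lists higher and 24 lower. It called some lists that camera did not. Drug resistance genes and flocculin and PAU genes were called higher (fry adjusted p = 0.00696 and 0.00271). The furan aldehyde enzyme list and the oxidative stress list were called lower (fry adjusted p = 0.0167 and 0.00299). What else set the counts of these tests apart was not tested. Leaving out 1 replicate at a time gave 855 to 1023 genes higher and 868 to 1117 lower, 15 to 21 higher and 24 to 49 lower at 2-fold or more, 5 to 7 lists higher and 9 to 12 lower. With the replicate block, counts were 774 and 810 genes, 21 and 33 at 2-fold or more, and 6 and 11 lists. Arrays of the same number did not deviate together (r = -0.248 to -0.199). Deviations from a mean of 3 arrays depend on each other, so this cannot show whether the numbers pair the cultures. Of 205 called named genes, 165 kept their call in every setting other than the stricter threshold. The 40 others included large changes: TKL2 (log2 fold change -1.19) and HXT3 (-0.96) lost the call in 5 settings each, FET3 (-0.93) in 4, and DDR2 (-1.37) and AGA2 (-0.93) in 3. PDR3 (0.17) and STB5 (0.15) lost it in 5 and GCN4 (-0.13) with the block. Robust moderation was not run for lists, and testing all probe sets separately gave counts of genes alone. For 70 genes with no signal above background on any array no change could be measured.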

Other observations

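The tests of glucose repression and of the permease family below were chosen after the result was seen. For the oxygen, glucose and cell cycle tests, conditions on the spread or on a wider gene set were added after their values were seen. Standard errors given beside medians below are those of the mean over genes or pairs, taken as independent, and serve as a rough measure alone. Bounds of the oxygen and family tests of hypoxic genes were set when the list's mean and the value of ANB1 were already known.

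Of 24 G2/M and cytokinesis genes 3 rose, 5 fell and 16 were not called (camera adjusted p = 0.946). The cyclin gene CLB1 fell by 1.00 on the log2 scale, and the cell wall enzyme genes DSE2, SCW11 and CTS1 fell by 0.64, 0.60 and 0.56. Of 30 G1/S and replication genes 5 rose and 7 fell (camera adjusted p = 0.581), with the G1 cyclin gene CLN1 up at a log2 fold change of 0.90. Among 37 meiosis and sporulation genes 8 rose and 3 fell (camera adjusted p = 0.443), and SPS4 rose by 1.08. DNA damage genes gave 5 rises and 8 falls among 23 (camera adjusted p = 0.493). Adjusted over the list alone, meiosis and sporulation gave 6 rises and 2 falls, and the other counts here were the same.

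Metal, vitamin and lipid genes moved both ways. The iron regulon gave 4 rises and 10 falls among 31 (camera adjusted p = 0.353), with the siderophore transporter gene SIT1 at -0.53, the phosphate regulon 4 and 7 among 18 (camera adjusted p = 0.946), and the zinc regulon 2 and 6 among 16 (camera adjusted p = 0.0985). Thiamine and vitamin B6 genes gave 4 rises and 8 falls among 20 (camera adjusted p = 0.177), pyrimidine genes 4 and 2 among 14 (camera adjusted p = 0.493), and NAD and NADPH supply genes 5 and 8 among 22 (camera adjusted p = 0.493). Glutathione and methylglyoxal genes gave 3 rises and 9 falls among 21 (camera adjusted p = 0.147), and GTT1, a glutathione transferase gene, fell by 0.80. Phospholipid and fatty acid genes gave 1 rise and 9 falls among 24 (camera adjusted p = 0.0778), vacuolar ATPase genes 6 and 3 among 18 (camera adjusted p = 0.413), translation factor genes 9 and 4 among 35 (camera adjusted p = 0.197), and unfolded protein response genes 6 and 3 among 26 (camera adjusted p = 0.769). Adjusted over the list alone, the counts were 5 and 7 for phosphate, 5 and 9 for thiamine and vitamin B6, and 6 and 9 for NAD and NADPH supply, and those of the other lists of this kind were the same.

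The rise of hypoxic genes beside the fall of respiratory genes is the second pattern weighed. Cross-hybridization among PAU, TIR and DAN genes stays open, since list members outside that family had a mean of 0.05947 with a standard error of 0.1401, although TIR2 and DAN4 rose on probe sets not marked as able to cross-hybridize. Both groups were grown without oxygen per the labels, so less oxygen in the inhibitor cultures could concern traces alone. Over 5 pairs of hypoxic and aerobic isoform genes the median difference was -0.1034, with 2 of 5 pairs higher in the hypoxic partner. This met the bound first set against the explanation, but by less than the standard error over pairs of 0.319, because ANB1 and AAC3 rose and COX5B and CYC7 fell. For stronger glucose repression the median over 11 repressed genes, -0.02643 (standard error 0.0532), met the bound first set against it by more than that error. Over 25 genes, with the gluconeogenesis list and its called members added, the median was -0.08 (standard error 0.0504), within the error of that bound, so it is left open.

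For the rise of FLO11 and SFG1 beside the falls of DSE2, SCW11 and CTS1, a shift in cell cycle phase was tested as a hypothesis on members of the G2/M list, whose result as a list was already known. The median log2 fold change over 12 such genes was 0.08996 (standard error 0.0385), with BUD8 and CHS2 called higher at 0.23 and 0.19. This met the bound first set against a shift, from -0.1 to 0.1, but lay within the standard error given of the upper end. These 12 leave out CLB1, DSE2, SCW11 and CTS1, which fell, and the whole list had a median of 0.02 with 5 genes lower, so the test leaves a shift in phase open.

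Several amino acid permease genes fell, which raised the hypothesis that the family falls as a whole. Of 20 members 13 fell and 1 rose, but 8 of them had been seen before the family was put together. Among the other 12, 5 fell and 1 rose, or 41.7% falling against 22.1% of other genes, which did not pass a two-sided Fisher's exact test (p = 0.154, odds ratio 2.51, interval 0.628 to 9.22), so the hypothesis stays open. Lower output of the SPS sensor of external amino acids, as a cause shared by its targets, was tested on 4 targets not seen before. Their median was 0.1692 (standard error 0.205), above the bound of -0.1 set against the explanation by more than that error. These 4 did not fall together: TAT2 fell, PTR2 rose, and BAP2 and TAT1 were not called. BAP3, GNP1, DIP5 and AGP1, whose falls of 1.61, 1.58, 1.23 and 0.87 raised the hypothesis, were left out. The test therefore cannot decide on the sensor, and an effect limited to the genes left out was not tested.

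Genes with large changes may be concentrated near chromosome ends. Among the 20 genes nearest each end of the 16 chromosomes, by gene order in assembly R64, 16 of 503 tested genes changed by 2-fold or more, or 3.18%, against 41 of 4946 elsewhere, or 0.829% (two-sided Fisher's exact test, p = 3.54e-05, odds ratio 3.93). Without cross-hybridizing probe sets the p was 3.46e-05. Genes are not independent, and neighbours or members of 1 family can change together, so this remains a hypothesis found and tested on the same data.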
